A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

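RNA of 4 cultures of the pressure-sensitive strain a924E1 and 4 of its parent KA31a was measured. Per the labels' protocols, 0.5 µg of total RNA was copied to cDNA, transcribed to Cy5-labelled cRNA and hybridised to 1 array per sample. Per the file headers, the 8 arrays were scanned at 635 nm with a pixel size of 5 µm and read with GenePix Pro 6.1.0.4, with local background and no normalization, and the deposited scanner tables hold spot intensity on a linear scale. The photomultiplier gain was 600 or 700, per the file headers, which settles the last number of each sample title. The arrays were those of 1 slide, in 2 columns and 4 rows by the block numbers and spot positions in the files. GenePix also gave each spot a signal-to-noise score and a percent of saturated pixels in the same deposited tables. The deposited files list 12512 spots per array, 2 for each of 6256 probes, and hold no control spots. The array build is not given in the sources used here.

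A value table deposited by the authors holds intensity per probe for the same arrays. Its scale was worked out from its values: it equals the quantile-normalized spot median less about 32.3 units, with negative values set to 0 and the 2 spots averaged, linear and not centred. Each column matched its own array at a Spearman correlation of 0.998 or more across probes. Column medians were 75.2, 75.1, 78.4 and 79.4 for mutants 1, 3, 5 and 7, and 76.6, 76.1, 77.0 and 75.5 for parents 2, 4, 6 and 8. How the authors chose the subtracted constant stays unknown. The table served as an alternative, as log2(value + 50).

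For the main values, spot medians were corrected for background with normexp (offset 50) in limma 3.58.1 under R 4.3.3, taken to log2, quantile-normalized between arrays and averaged over the 2 spots of a probe. Each gene has 1 probe. Fold changes on this scale understate changes of dim genes because of the offset. Spots that GenePix did not find (3.60% to 26.8% per array) were kept, since they mark dim spots. A probe counted as above background on an array when both spots had a signal-to-noise ratio of at least 3. For a gene at background on every array of 1 strain, only a lower bound of the fold is given: the brighter strain's mean log2 level minus the mean, per array of the dimmer strain, of the higher of the lowest level above background and the gene's own level. Of 6256 systematic names, 5756 were in a table of reference assembly R64 and 500 were not. That table was used only for names, for each gene's chromosome and for which genes are neighbours. Gene names are otherwise those of the scanner files.

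Mutant and parent were compared with limma's lmFit and eBayes on 4 against 4 arrays, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with calls at 0.05. All adjusted p-values of genes are from this model. No labels pair the samples. The 40 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With the preset correlation 15 lists passed, 5 higher and 10 lower, and with an estimated correlation 6 (cytosolic ribosome, ribosome biogenesis, amino acid synthesis, mitochondrial ribosome, glycolysis and fermentation, gluconeogenesis and glyoxylate cycle). In fry, which does not compare a list with other genes, 29 of the 40 passed. Only 1 list member was not measured. A member's count "adjusted over the list alone" adjusts p over that list's members. The groups, lists, tests, alternative settings and rule for named genes were fixed before the data were examined.

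Named genes were the 12 largest rises and 12 largest falls among called genes whose strains did not overlap and that were above background on all 4 arrays of the higher strain. To these came up to 4 called members of each list with the smallest adjusted p, and all measured members of the lists of mitochondrial genome, laboratory markers, a-specific and alpha-specific genes. This made 173 genes, of which the text gives a part, and 1 result among them is not reported here. Genes outside this rule are said to be so where they appear, except members of a list given as not passing.

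The same steps were tested on simulated data made from these arrays' values, 4 against 4, with 6256 genes. Of 50 genes changed by a true log2 of 0.5, 41 were called, and 50 of 50 at each of 1, 2 and 3. The median estimates for true sizes of 0.5, 1, 2 and 3 were 0.32, 0.67, 1.44 and 2.21, so sizes were understated. Of unchanged genes, 12 (0.198%) were called. A list lowered by a log2 of 0.5 on the already normalized values was called, and 0 of 40 random lists were (camera). The size of the noise was preset and not fitted to the spread between these arrays, so these rates need not hold for the real data. Noise was drawn for each gene separately, so the simulated genes of a list were not correlated. The random lists therefore do not show how camera at the preset correlation treats correlated genes. The changed genes were all brighter than the median gene.

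The alternative settings fixed beforehand were no background correction, plain subtraction, normexp with an offset of 16, scaling to the 75th percentile or the median, cyclic loess, a filter on genes above background on all 4 arrays of a strain, scanner gain as a block and within each gain, slide row and pairs of slide rows as a block, trended and robust variance, array quality weights, the authors' deposited intensity table, and leaving out each sample. Those added after seeing the data were the mean of a spot's pixels, mutants 1 and 3 averaged as 1 sample, these together with parents 6 and 8 or with parents 4, 6 and 8 averaged as 1 sample, and a filter on genes above background on all 8 arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No sample was left out, and 1 spot with saturated pixels was kept.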

Results

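Transcript levels were measured on 8 one-colour arrays, 4 of the pressure-sensitive budding yeast mutant a924E1 and 4 of its parent strain KA31a. Both strains had grown for 48 h at 30 °C in rich glucose medium, with no pressure treatment named in the labels. The comparison asks which transcripts differ between mutant and parent in such cultures. The design text describes independent biological samples. Each array read 6256 probes, 1 per gene, in 2 spots each. Median signal over local background was 82, 112, 16 and 5 intensity units on mutant arrays 1, 3, 5 and 7, and 163, 182, 54 and 15 units on parent arrays 2, 4, 6 and 8. Probes above background numbered 4435, 4704, 1526 and 602 on the mutant arrays and 5086, 5272, 4281 and 1534 on the parent arrays. Mutant 5, mutant 7 and parent 8 were scanned at the higher gain of 700 and were still the dimmest, so many genes below are above background on only 2 or 3 mutant arrays. The number of arrays limits the precision of every value.

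After quantile normalization the first principal component, with 60.5% of the variance, held the mutant arrays between -21.8 and -15.3 and the parent arrays between 15.2 and 21.5. Pearson's r across genes was 0.932 to 0.996 within the mutant, 0.959 to 0.989 within the parent and 0.869 to 0.939 between strains. Over probes above background on all 8 arrays, mutants 1 and 3 differed by 0.363 of the variance expected from duplicate spots, and parents 6 and 8 by 0.226. These 2 pairs were closer than the other mutant pairs, at 0.634 to 1.02, and the other parent pairs, at 0.619 to 1.36. The design text describes separate samples, so all 8 arrays were kept apart. In all, 5 of 6 mutant pairs and 3 of 6 parent pairs differed by less than duplicate spots do. Independent spot noise would give a ratio of about 1 even for 1 RNA on 2 arrays. Duplicate spots thus overstate the noise between arrays, and this measure cannot tell shared RNA from separate cultures. If any of these arrays share RNA, the number of samples is overstated and the p-values measure partly technical spread. The mutant arrays of gain 600 were only mutants 1 and 3. Every count, p-value and bound within gain 600 therefore rests on this close pair for the mutant, with the same doubt. Averaging each of the 2 closest pairs as 1 sample gave 1145 called genes, 497 higher and 648 lower. All 4 mutant arrays lay in 1 column of the slide and all 4 parent arrays in the other, so slide column and strain cannot be told apart.

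The mutant expressed far less of several genes for growth on acetate and ethanol. More moderately, it expressed less of the genes for the cytosolic ribosome (log2 list median -0.87) and more of those for the mitochondrial ribosome (0.53). YAT1, a mitochondrial carnitine acetyltransferase, was 39.9-fold lower, and ICL1, isocitrate lyase of the glyoxylate cycle, was 34.3-fold lower. FBP1, the gluconeogenic bisphosphatase, was 19.2-fold lower. Among the largest rises were SUC2, the secreted invertase, at 3.19-fold, and COX1, the mitochondrially encoded core subunit of cytochrome oxidase, at 2.39-fold. Across all 6256 genes, limma called 1667 at an adjusted p under 0.05, of which 794 were higher and 873 lower in the mutant. Of these, 243 differed at least 2-fold, 61 higher and 182 lower. The 4 mutant values lay entirely above or below the 4 parent values for 1873 genes, or 29.9%, where chance gives 2.86%. Of the called genes, 632 were above background on all 4 arrays of the higher strain, 213 of them higher and 419 lower. That filter favours lower calls, since 1525 genes were above background on all parent arrays and 593 on all mutant arrays. Called genes above background on all 8 arrays were 202 higher (67.3%) and 98 lower. Of all 582 genes that pass this filter, called or not, 375 (64.4%) read higher and 207 lower. The excess of higher calls is thus near the share that the filter itself gives. Of 901 probes at or below background on all 8 arrays 787 read higher in the mutant, as did all 10 of them that were called, so these 10 calls are no evidence of a rise. The call count depended on the scaling: with 75th percentile scaling 57 genes passed, 0 higher and 57 lower (limma, 760 at an unadjusted p under 0.05), and with median scaling 37, 0 higher and 37 lower (751 unadjusted). Scanner gain as a block gave 1626 genes, the 5 arrays of gain 600 alone gave 1949, and the 3 arrays of gain 700 alone gave 0 by limma (647 unadjusted), while slide row as a block gave 1786. Array weights gave 3034 (1653 higher, 1381 lower). The weights were 3.15, 7.85, 0.24 and 0.16 for mutants 1, 3, 5 and 7, and 0.61, 2.16, 1.60 and 0.49 for parents 2, 4, 6 and 8. Calls with array weights thus rest mostly on the close pair of mutants 1 and 3 for the mutant. Averaging mutants 1 and 3 as 1 sample and parents 4, 6 and 8 as 1 sample gave 630 (242 higher, 388 lower).

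The glyoxylate cycle and gluconeogenesis fell together. Of 17 measured genes of this list 14 fell, 0 rose and 3 did not pass, with 14 lower adjusted over the list alone. The log2 level of ICL1 fell by 5.10 ± 0.11 (SE, n = 4 per strain, limma adjusted p = 1.7e-10), and it was above background on 2 of 4 mutant and 4 of 4 parent arrays. FBP1 differed by -4.26 ± 0.11 (adjusted p = 9.43e-10) and MLS1, malate synthase, by -3.75, or 13.4-fold (adjusted p = 1.02e-08), both above background on 2 mutant arrays. SFC1, the mitochondrial exchanger of succinate and fumarate, was above background on no mutant array and was at least 10.3-fold lower (adjusted p = 5.92e-08). ADH2, the alcohol dehydrogenase that oxidises ethanol, was 9.70-fold lower (adjusted p = 1.05e-05), and CIT2, peroxisomal citrate synthase, was 3.62-fold lower (adjusted p = 2.93e-05). ICL2, ALD4 and CAT2 did not pass. Over the list, the median was -1.66 (camera adjusted p = 6.04e-15, and 0.00406 with an estimated correlation). It was -1.93 within gain 600, -1.18 within gain 700 and -1.67 with gain as a block. Among genes above background on all 8 arrays, which leaves out those at background in the mutant, it was -0.87 (camera adjusted p = 0.000204).

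**Figure D1:**
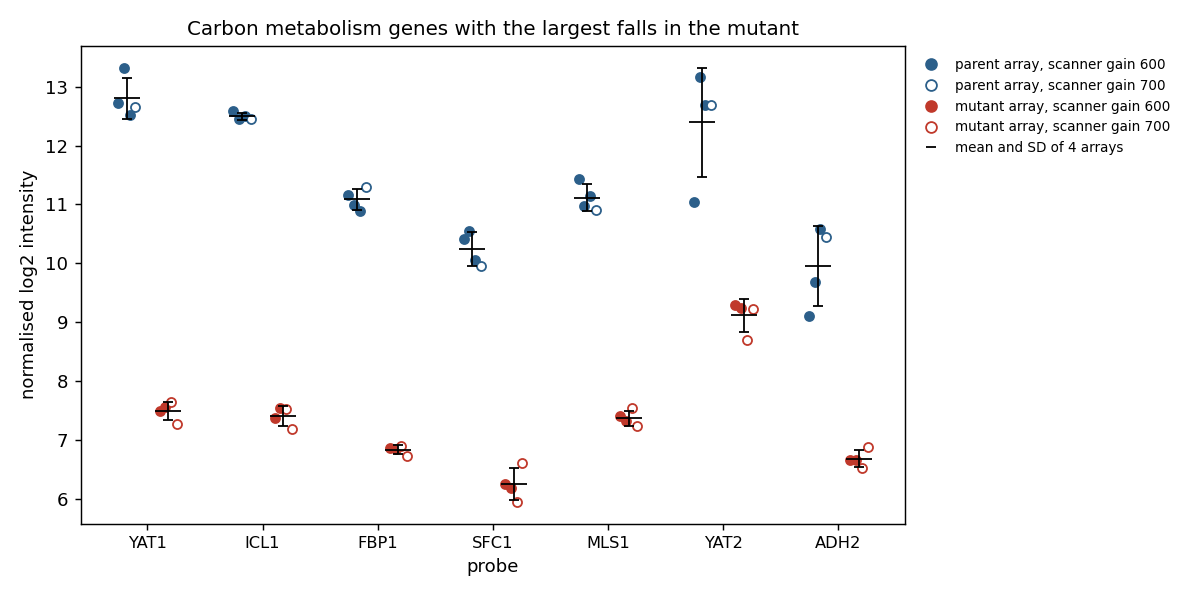
Normalized log2 signal (vertical axis) of 7 genes of acetate, ethanol and carnitine metabolism on each of the 4 mutant and 4 parent arrays, with the mean and SD of each strain; open symbols mark arrays scanned at gain 700. All mutant values lie below all parent values for each gene, with YAT1 lower by 39.9-fold and ADH2 by 9.70-fold, and SFC1 is above background on no mutant array.

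Of the genes for carnitine acetyltransfer and transport, 3 fell and CAT2, at -0.14, did not pass. YAT1 differed by -5.32 ± 0.17 (SE, n = 4 per strain, limma adjusted p = 3.84e-09), from a mean log2 level of 12.81 in the parent to 7.49 in the mutant, and was above background on 3 mutant arrays. YAT2, a second carnitine acetyltransferase, was 9.75-fold lower (adjusted p = 8.55e-05), and CRC1, the mitochondrial carnitine carrier, differed by -1.57 (adjusted p = 0.000134). These genes are in the list of peroxisome and fatty acid oxidation, of which 2 of 24 measured genes rose, 6 fell and 16 did not pass, with 4 higher and 6 lower adjusted over the list alone. SPS19, a peroxisomal reductase of fatty acid oxidation, also fell, by 1.18, whereas FOX2, the multifunctional enzyme of beta-oxidation, named after its value was seen, rose by 0.75. The list as a whole did not pass (camera adjusted p = 0.380, but 0.0283 with median scaling), and its signs differed, with a median of 0.04, a mean of -0.38 and a test direction of lower.

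Genes for the cytosolic ribosome fell across the list. Of 139 measured genes 114 fell, 0 rose and 25 did not pass, with 120 lower adjusted over the list alone. RPS3 was 6.45-fold lower, RPS17B 4.01-fold and RPS0A 2.99-fold, each above background on 2 mutant and 4 parent arrays. The list median was -0.87 (camera adjusted p = 3.3e-42, and 0.00406 with an estimated correlation), -1.01 within gain 600, -0.50 within gain 700 and -0.83 with gain as a block. Within the 4 slide rows, each with 1 mutant and 1 parent array, the median ran from -0.93 to -0.84. Of 47 ribosome biogenesis genes 26 fell, 0 rose and 21 did not pass, with 32 lower adjusted over the list alone. NSR1, a nucleolar protein of rRNA processing, was 5.07-fold lower, and RLP7 differed by -1.51. That list's median was -0.41 (camera adjusted p = 5.24e-14, and 0.0188 with an estimated correlation), -0.68 within gain 600 and -0.10 within gain 700. Probes for paralogous ribosomal protein genes can bind each other's transcripts, so the value of a single such gene is uncertain.

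Amino acid synthesis fell. Of 59 measured genes 29 fell, 4 rose and 26 did not pass, with 34 lower and 6 higher adjusted over the list alone. ILV5, acetohydroxyacid reductoisomerase, was 6.06-fold lower (adjusted p = 5.92e-08), LEU4, isopropylmalate synthase, 5.93-fold (adjusted p = 1.54e-05), and BAT1, the mitochondrial branched-chain aminotransferase, 4.74-fold (adjusted p = 2.34e-06). ARG3 of arginine synthesis, above background on no mutant array, was at least 1.48-fold lower. The 4 genes that rose, named after their values were seen, were HIS2 by 0.82, LYS9 by 0.71, LYS1 by 0.46 and CYS3 by 0.42. Over the list, the median was -0.35 (camera adjusted p = 3.5e-08, and 0.0163 with an estimated correlation), -0.41 within gain 600 and -0.13 within gain 700.

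In glycolysis and fermentation, 17 of 28 genes fell, 3 rose and 8 did not pass, with 18 lower and 4 higher adjusted over the list alone. FBA1, aldolase, was 3.20-fold lower and GPP1, a glycerol phosphatase, 4.73-fold lower. PDC6, a minor pyruvate decarboxylase, was at least 1.84-fold lower. TDH1, a glyceraldehyde phosphate dehydrogenase, rose by 0.83, and so did the glucose-phosphorylating HXK1 by 0.89 and GLK1 by 1.17, these last genes named after their values were seen. The list median was -0.49 (camera adjusted p = 0.000251, and 0.0262 with an estimated correlation), -0.53 within gain 600 and -0.39 within gain 700. Storage carbohydrate genes moved the other way: 11 of 17 trehalose and glycogen genes rose, 0 fell and 6 did not pass, with 13 higher adjusted over the list alone. GPH1, glycogen phosphorylase, was 2.35-fold higher, GSY2, glycogen synthase, rose by 1.04 and GDB1, the debranching enzyme, by 0.97. Over the list, the median was 0.52 (camera adjusted p = 1.86e-05, but adjusted p = 0.0754 with an estimated correlation), 0.71 within gain 600 and 0.34 within gain 700, and the call ended with median scaling (adjusted p = 0.113).

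Nuclear genes for mitochondrial function were tested in several lists, which were not compared with each other. Of 70 mitochondrial ribosome genes 43 rose, 0 fell and 27 did not pass, with 49 higher adjusted over the list alone. MRPL1 rose by 1.10, MRPL40 by 0.95 and MRPS5 by 0.86. The list median was 0.53 (camera adjusted p = 4.11e-13, and 0.0171 with an estimated correlation), 0.67 within gain 600 and 0.35 within gain 700. Of 30 genes for cytochrome oxidase assembly and COX1 expression 15 rose, 1 fell and 14 did not pass, with 17 higher and 1 lower adjusted over the list alone. COX17, a copper chaperone, was 2.65-fold higher (adjusted p = 1.18e-05), SCO1, which also delivers copper to the oxidase, rose by 1.21, and MRS1, a splicing factor of mitochondrial introns, by 1.05. COX20, named after its value was seen, was the gene that fell, by 0.65. Over the list, the median was 0.42 (camera adjusted p = 8.16e-05, but adjusted p = 0.0678 with an estimated correlation), 0.61 within gain 600 and 0.15 within gain 700. This call ended among genes above background on all 4 arrays of a strain (median 0.36, camera adjusted p = 0.137) and on all 8 arrays (0.39, 0.717). Of 10 coenzyme Q genes 6 rose, 0 fell and 4 did not pass, with 7 higher adjusted over the list alone, and COQ1 rose by 1.04 and COQ3 by 0.95 (list median 0.44, 0.62 within gain 600 and 0.24 within gain 700, camera adjusted p = 0.00311, but adjusted p = 0.148 with an estimated correlation). Of 28 mitochondrial import genes 9 rose, 0 fell and 19 did not pass, with 9 higher adjusted over the list alone, and MIA40 rose by 1.11 (list median 0.27, 0.26 within gain 600 and 0.16 within gain 700, camera adjusted p = 0.0107, but adjusted p = 0.0754 with an estimated correlation and 0.0846 with median scaling, and a median of 0.07 at 0.949 among genes above background on all 8 arrays).

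Among genes for the respiratory chain and ATP synthase, more fell than rose, and many did not pass. Of 24 genes of complexes II to IV 9 fell, 3 rose and 12 did not pass, with 13 lower and 3 higher adjusted over the list alone. COX7 was 3.49-fold lower, COX5A differed by -1.25 and SDH2 of succinate dehydrogenase by -1.34 (adjusted p = 0.00149, and 0.05004 within gain 600), while CYC7, an isoform of cytochrome c, rose by 1.15. COR1 at 0.49 and QCR2 at 0.37, named after their values were seen, were the other members that rose. The list median was -0.34 (camera adjusted p = 0.000251, but adjusted p = 0.148 with an estimated correlation), -0.32 within gain 600 and -0.40 within gain 700. Of 20 ATP synthase genes 9 fell, 3 rose and 8 did not pass, with 9 lower and 3 higher adjusted over the list alone. ATP17 differed by -1.44 and ATP15 by -0.98, whereas the assembly factors ATP11 at 0.76 and ATP12 at 0.42 and the stabilising factor STF2 at 1.02 rose, these 3 named after their values were seen. That list's median was -0.25 (camera adjusted p = 0.0282, but adjusted p = 0.122 with an estimated correlation and 0.0912 within gain 600). It was -0.31 within gain 600 and -0.20 within gain 700. Among genes above background on all 8 arrays it was 0.02 (camera adjusted p = 0.806), where the median of all genes was 0.20. Of 9 retrograde response genes 6 fell, 1 rose and 2 did not pass, with 6 lower and 1 higher adjusted over the list alone. DLD3 differed by -1.46 and PYC1 by -1.13, ATO3 was at least 1.64-fold lower, and IDH1 rose by 0.55 (list median -1.13, -1.18 within gain 600 and -0.54 within gain 700, camera adjusted p = 0.00255, but adjusted p = 0.128 with an estimated correlation). With genes above background on all 4 arrays of a strain this median was -0.78 (adjusted p = 0.202), and on all 8 arrays -0.24 (0.163). In the TCA cycle 7 of 17 genes fell and 3 rose, with 7 lower and 3 higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.137), but it passed with 75th percentile scaling (0.00259) and median scaling (0.0170). CIT3, a mitochondrial citrate synthase, differed by -0.84. In heme synthesis HEM15, ferrochelatase, rose by 1.11 and HEM1, the first enzyme, fell by 0.75. There 4 of 8 genes rose and 1 fell, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0682, and 0.0391 without mutant 7 and 0.0372 with 75th percentile scaling).

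**Figure D2:**
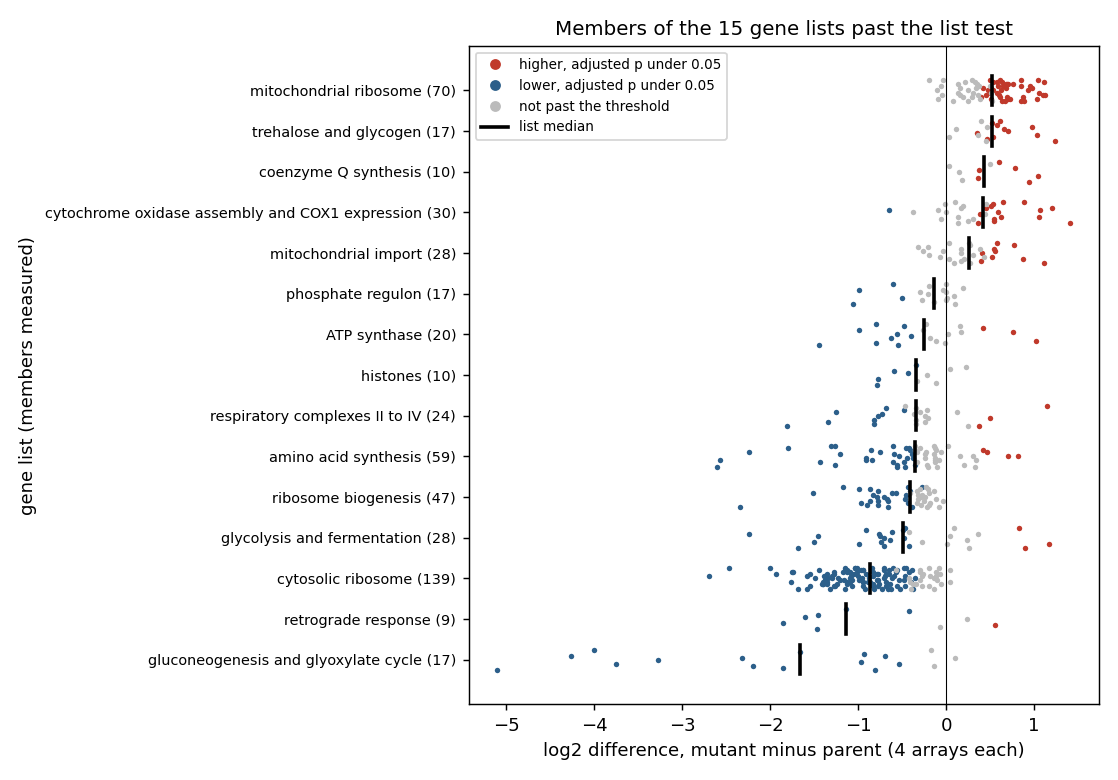
Log2 difference, mutant minus parent, of each measured member (points) of the 15 gene lists that passed the list test, with the list median as a bar; red is higher, blue lower and grey not past the threshold in limma with 4 arrays per strain. List medians run from -1.66 for gluconeogenesis and the glyoxylate cycle to 0.53 for the mitochondrial ribosome. The median of the phosphate regulon, -0.14, is 0.06 with 75th percentile scaling, where the median of all genes is 0.21.

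Probes on the mitochondrial genome did not move together. COX1 rose by 1.25 ± 0.18 (SE, n = 4 per strain, limma adjusted p = 0.000442), and was above background on all 8 arrays. Its call ended with 75th percentile and median scaling, while its estimate stayed between 1.06 and 1.42 under every alternative. The other genes were COX2 at 0.07, COX3 at -0.25, COB at 0.14, ATP6 at -0.23, ATP8 at -0.03 and OLI1 at -0.02, none past the threshold (adjusted p from 0.241 to 0.943). COX2 did pass within gain 600, at 0.42 (adjusted p = 0.0227), and with array weights, at 0.27 (0.0131), as did COX3 with array weights, at -0.33 (0.0134). VAR1 was called at 0.28 (adjusted p = 0.0472), but it was below background on all 8 arrays, where most probes read higher in the mutant, so its value is no evidence of a rise. That call ended with slide row as a block (adjusted p = 0.0641), and without any 1 of mutant 1 (0.112), mutant 3 (0.0863), parent 2 (0.0756), parent 4 (0.123), parent 6 (0.0957) or parent 8 (0.0903). Of 8 genes 2 were thus called higher, VAR1 included, with 2 higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.625). Of 6 probes named for reading frames in COX1 introns, 3 were lower in the mutant, AI1 did not pass, and AI3 and AI4 were at background on all 8 arrays. AI5_ALPHA was above background on 4 parent and 0 mutant arrays and was at least 3.63-fold lower (adjusted p = 2.2e-07). Its call ended with 75th percentile scaling, though it read lower in the mutant under every alternative in which it was tested. AI2, above background on 3 parent and 0 mutant arrays, was at least 1.51-fold lower (adjusted p = 1.78e-05). AI5_BETA, likewise above background on 3 parent and 0 mutant arrays, was called lower (adjusted p = 0.00888), too near background for a bound on its fold over all 8 arrays. AI1 differed by 0.55 (adjusted p = 0.0559, not past the threshold). AI1 to AI4 and AI5_BETA lie outside the rule for named genes and were chosen after their values were seen.

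**Figure D3:**
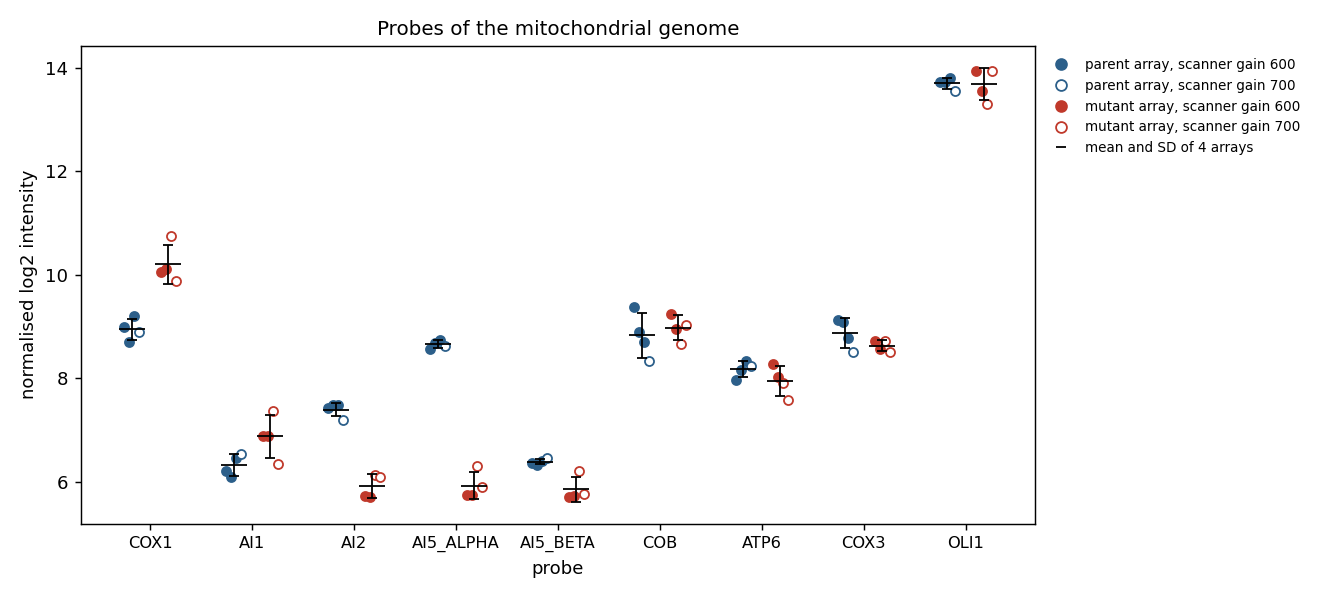
Normalized log2 signal (vertical axis) of COX1, its intron probes and 4 other mitochondrial genes on each of the 4 mutant and 4 parent arrays, with the mean and SD of each strain; open symbols mark arrays scanned at gain 700. COX1 is 2.39-fold higher in the mutant, while AI2, AI5_ALPHA and AI5_BETA are above background on no mutant array.

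Other large single-gene changes belonged to several pathways. ALD3, a cytosolic aldehyde dehydrogenase, was 3.04-fold higher and CAR1, arginase, 2.90-fold higher. LAP2, ODC2, PIR1, XKS1, ABZ1 and MSF1 rose between 2.33-fold and 2.58-fold. SUC2 (1.67, adjusted p = 0.000152) and CAR1 (1.54, adjusted p = 0.00417) were above background on all 4 mutant arrays. SPS100, a spore wall protein, was 5.65-fold lower, and was 1 of the 22 meiosis and sporulation genes, of which 1 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.331). HXT5, a hexose transporter, was 5.56-fold lower and HXT7 rose by 0.61. That made 1 lower and 1 higher of 18 hexose transport genes, with 1 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.302). HXT7 no longer passed with gain as a block (adjusted p = 0.0554), within gain 600 (0.0885), or without mutant 1 (0.0593), mutant 5 (0.0879), mutant 7 (0.0535), parent 2 (0.0725) or parent 4 (0.0963).

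Stress and wall genes moved both ways. Of 25 stationary phase genes 11 fell and 5 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0869, but 0.00279 with 75th percentile and 0.00344 with median scaling, and 0.0421 within gain 700): GRE1 differed by -2.08 and SNZ1 by -1.84, while HSP12 rose by 1.16 and YGP1 by 0.97. Of 32 heat shock protein genes 7 rose and 7 fell, with 8 and 8 adjusted over the list alone (camera adjusted p = 0.302, but 0.0143 and 0.0170 with these scalings), YDJ1 differing by -0.88. In oxidative stress defence 7 of 28 genes rose and 6 fell, with the same counts adjusted over the list alone. TSA2 rose by 1.05 and OYE3 fell by 1.08 (camera adjusted p = 0.744; the median was 0.02, the mean -0.02 and the test direction lower). For the cell wall 15 of 36 genes rose and 5 fell, with 16 higher and 5 lower adjusted over the list alone. EGT2 rose by 1.21 and GSC2, a glucan synthase subunit, fell by 1.65. This list stood at a camera adjusted p of 0.0509, and passed with slide row as a block (0.0437) or array weights (0.0463), and without mutant 7 (0.0407), parent 6 (0.0247) or parent 8 (0.0394). Proteasome genes numbered 1 higher and 4 lower of 33, with 1 and 3 adjusted over the list alone (RPT3 -0.58, camera adjusted p = 0.609). Autophagy had 6 higher and 2 lower of 31, with the same counts adjusted over the list alone (ATG19 0.76, camera adjusted p = 0.207).

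Lipid, nutrient and drug resistance lists mostly did not pass. Ergosterol synthesis had 7 lower and 4 higher of 25, with 8 and 4 adjusted over the list alone (ERG25 -1.50 and ERG3 -1.08, camera adjusted p = 0.238, but 0.0212 with median scaling). Fatty acid and phospholipid synthesis had 4 higher and 3 lower of 25, with 5 and 4 adjusted over the list alone (PIS1 0.94 and OLE1 -1.15, camera adjusted p = 0.364). Hypoxic and anaerobic genes numbered 2 higher and 2 lower of 21, with the same counts adjusted over the list alone (camera adjusted p = 0.808). Pleiotropic drug resistance had 3 higher and 1 lower of 18, with 4 and 1 adjusted over the list alone (PDR15 1.10, camera adjusted p = 0.293). For the iron regulon 2 of 27 genes rose and 1 fell, with 0 adjusted over the list alone (camera adjusted p = 0.834; the median was 0.02, the mean -0.01 and the test direction lower). Of 23 sulfur assimilation genes 3 rose and 4 fell, with 3 and 6 adjusted over the list alone (camera adjusted p = 0.331). Nitrogen catabolite repressed genes had 8 higher and 3 lower of 25, with 9 and 3 adjusted over the list alone (CAR1 1.54, DUR12 1.06, MEP2 -0.81 and PUT1 -0.94, camera adjusted p = 0.457). The phosphate regulon passed with 4 lower and 0 higher of 17, and the same counts adjusted over the list alone. VTC1 differed by -1.05 and PHO89 was at least 1.32-fold lower (list median -0.14, camera adjusted p = 0.0427, but adjusted p = 0.146 with an estimated correlation). That call ended within gain 600 (adjusted p = 0.0912), with array weights (0.114), and without mutant 5 (0.0972), parent 2 (0.0698) or parent 6 (0.0534). Within gain 700 the list median was -0.05. With 75th percentile scaling it was 0.06, but the median of all genes was then 0.21. Relative to all genes the list stood at -0.15, against -0.19 with the main values. With scanner gain or slide row as a block, each of the 15 lists passed in the same direction, with a highest adjusted p of 0.0479 and 0.0464, both of the phosphate regulon, and 1 further list passed with each: the a-specific genes with gain and the cell wall with slide row.

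Histone genes fell in 5 of 10 cases and rose in 0, with 5 lower adjusted over the list alone. HHT1 and HHF1, an adjacent pair for histones H3 and H4, differed by -0.79 and -0.78, and HHF1 did not pass within gain 600 (adjusted p = 0.0595; list median -0.34, -0.35 within gain 600 and -0.19 within gain 700, camera adjusted p = 0.0182, but adjusted p = 0.148 with an estimated correlation). In the DNA damage list 5 of 22 genes fell and 1 rose, with the same counts adjusted over the list alone (RNR2 -1.16, camera adjusted p = 0.293). Cell cycle genes had 5 higher and 2 lower of 30, with the same counts adjusted over the list alone (SIC1 0.91 and MCM3 -0.62, camera adjusted p = 0.457).

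Mating-type genes were compared between the strains, and such differences do not by themselves give either strain's cell type. Of 7 a-specific genes 3 rose and 0 fell, with 3 higher adjusted over the list alone: STE2, the alpha-factor receptor, by 0.58, ASG7 by 0.92 and BAR1 by 0.49, while MFA1 at 0.05, MFA2 at 0.00, AGA2 at 0.22 and STE6 at 0.32 did not pass. The list stood at a camera adjusted p of 0.0573, at 0.0424 with gain as a block, at 0.0215 with median scaling and at 0.0445 without mutant 5. STE6 passed with array weights (adjusted p = 0.0119) and without mutant 5 (0.0200). The BAR1 call (adjusted p = 0.0342) ended without mutant 1 (0.0922), mutant 3 (0.0842), mutant 5 (0.0772), parent 2 (0.0547), parent 4 (0.0939), parent 6 (0.0515) or parent 8 (0.0806). None of the 6 alpha-specific genes passed in limma or adjusted over the list alone (STE3 -0.16, SAG1 -0.17, HMLALPHA1 0.58, HMLALPHA2 -0.44, MF(ALPHA)1 0.12 and MF(ALPHA)2 0.08). That list had a median of -0.04, a mean of 0.000633 and a test direction of lower (camera adjusted p = 0.759). HMLALPHA1 passed within gain 600 (adjusted p = 0.0174), with array weights (0.0175) and without mutant 7 (0.0371), STE3 with array weights (0.0282) and HMLALPHA2 without parent 2 (0.0466). Of 17 haploid and pheromone genes 1 rose and 1 fell, with 1 lower and 0 higher adjusted over the list alone (FUS3 -0.53, not past the threshold within gain 600 at an adjusted p of 0.0509; camera adjusted p = 0.410).

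Of 8 genes used as markers in laboratory strains, LEU2 differed by -1.43 (limma adjusted p = 0.000232), ADE1 by -0.65 (adjusted p = 0.0291) and MET17, also known as MET15, by 0.61 (adjusted p = 0.0285). URA3 at -0.02, HIS3 at -0.12, TRP1 at -0.34, LYS2 at -0.23 and ADE2 at 0.12 did not pass. Thus 1 rose and 2 fell, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.238). ADE1 no longer passed within gain 600 (adjusted p = 0.131) or without mutant 5 (0.0529), mutant 7 (0.0615), parent 2 (0.0784) or parent 4 (0.0756), and MET17 with gain as a block (0.0526), within gain 600 (0.152) or without mutant 3 (0.0570), mutant 5 (0.0709), parent 2 (0.0683) or parent 8 (0.0745). TRP1 passed with slide row as a block (adjusted p = 0.0443), within gain 600 (0.0156) and without mutant 5 (0.0180), and URA3 passed within gain 600 at 0.40 (0.0300). With array weights TRP1 (adjusted p = 0.000529), HIS3 (0.0236) and URA3 (0.0120) passed.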

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

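In 29 of 430 groups of 4 arrays (6.74%; chance gives about 5%), 1 array stood apart from the other 3 by a gap whose share of the group's range exceeded Dixon's 95% critical value. No explanation was tested for them, and no test here was chosen after the result was seen. Each value below is that share of the range, for a gene or for the mean of a list.

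On mutant 5, scanned at gain 700, 8 values stood apart, of which 7 are given. The array read lowest for YAT2 (0.889), at a log2 level of 8.70 against 9.23 to 9.29 on the other mutant arrays, and also for GSC2 (0.842), MEP2 (0.844) and the mean of the coenzyme Q list (0.930). It read highest for SUC2 (0.879), at 10.59 against 9.79 to 9.89, for HEM15 (0.879) and for the mean of the nitrogen catabolite repressed list (0.833). On mutant 7, the dimmest array, 8 values stood apart. This array was highest for HMLALPHA1 (0.900), MFA1 (0.851), DAL7 (0.841), MF(ALPHA)1 (0.967) and the mean of the iron regulon (0.940), and lowest for CCC2 (0.839), SPS19 (0.8293) and ATG11 (0.853). All 7 of these genes were at background on mutant 7, where the lowest level above background is 7.97, so their values are background readings. Of these, HMLALPHA1 read 7.44 against 6.25 to 6.37 on the other mutant arrays.

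Mutant 1 was lowest for RPS0A (0.946), at 7.19 against 7.23 on the others, and mutant 3 was highest for GPP1 (0.870). Parent 2 was highest for SCO1 (0.889) and ATP18 (0.832) and lowest for MRPS5 (0.840), SWI5 (0.929), COQ6 (0.895) and the mean of the sulfur assimilation list (0.858). For COQ6 it read 6.73 against 7.23 to 7.28 on the other parent arrays. Parent 4 was highest for COX9 (0.968) and parent 6 for MEP2 (0.978). Parent 8, the parent array scanned at gain 700, was highest for TOM20 (0.938) and MF(ALPHA)1 (0.969) and lowest for the mean of the mitochondrial genome list (0.854), at 8.29 against 8.46 to 8.49. The values of MEP2 on mutant 5, SWI5 on parent 2 and TOM20 and MF(ALPHA)1 on parent 8 are background readings as well.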

How the results depend on the processing

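The pixel mean, the 3 averagings of arrays and the filter on all 8 arrays were chosen after seeing the data. The count of 1667 genes (794 higher, 873 lower, 243 at least 2-fold) moved by over 1.5 times with 75th percentile scaling (57 genes, 0 higher, 57 lower, 57 at least 2-fold) and median scaling (37, 0, 37 and 37). All-gene medians were then 0.21 and 0.15 against 0.05 with quantile normalization, and plain shifts leave the dim arrays' narrower spread in place. It moved with the filter on all 4 arrays of a strain (738 of 1536 tested, 310 and 428), the filter on all 8 arrays (298 of 582 tested, 200 and 98, 66 at least 2-fold, all-gene median 0.20), and array weights (3034, 1653 and 1381). With mutants 1 and 3 as 1 sample and parents 4, 6 and 8 as 1 sample, which leaves 3 samples against 2, it was 630 (242 and 388). With mutants 1 and 3 and parents 6 and 8 averaged in pairs it was 1145, of which the 497 higher moved and the 648 lower did not. Within gain 700, with 2 mutants and 1 parent, limma called 0 genes (0 higher, 0 lower, 0 at least 2-fold, 647 at an unadjusted p under 0.05). The 2-fold count was 406 with no background correction, 1014 with plain subtraction (all-gene median 0.12), 495 with the smaller offset, 421 within gain 600 and 407 with the deposited values. Both filters test fewer genes, and gain 700 and the averagings leave fewer samples. For the other moves the cause was not tested. Of the 1667 genes, 1589 were also called with the deposited values, 1516 with cyclic loess, 1604 with slide row as a block, 1531 with gain as a block and 1374 within gain 600. Leaving out 1 sample gave 1210 to 1708 genes (534 to 854 higher, 676 to 868 lower), 209 to 316 at least 2-fold and 14 to 17 lists.

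Of 40 lists 15 passed, 6 with an estimated correlation, 29 with fry, 6 of 34 tested with the filter on 4 arrays and 7 of 24 with that on 8 arrays. The cytosolic ribosome, ribosome biogenesis, amino acid, glycolysis, gluconeogenesis and mitochondrial ribosome lists passed under each alternative in which the list was tested with camera. A filter ended the respiratory complex, oxidase assembly, ATP synthase, retrograde, coenzyme Q, import, histone and phosphate calls. Plain subtraction ended those of ATP synthase (adjusted p = 0.0732), histones (0.0675) and the phosphate regulon (0.105). It gave medians of -1.40 for ribosome biogenesis, -1.55 for the cytosolic ribosome and -0.71 for amino acid synthesis, against -0.41, -0.87 and -0.35. The phosphate call also ended with both scalings, cyclic loess, array weights, within each gain and without 3 of the samples in turn. The 75th percentile and median scalings each passed 18 lists, both adding the TCA cycle, heat shock and stationary phase lists. The 75th percentile added heme, and the median peroxisome, ergosterol and a-specific genes, while it ended the import and trehalose calls. The correlation gap between and within strains was 0.0618, 0.171 with the filter on 4 arrays, 0.156 with that on 8 and 0.0572 to 0.0671 without 1 sample. URA3 at -0.02 turned to 0.40 within gain 600 (adjusted p = 0.0300) and 0.35 with array weights (0.0120), the cause not tested. Of 173 named genes, 130 no longer passed with 75th percentile scaling, 132 with median scaling, 152 within gain 700, 42 with the larger averaging, 17 with plain subtraction and 15 within gain 600, all in the same direction. The labels pair no samples. Slide row, which joins 1 array of each strain, was run as a block instead (1786 genes, 16 lists). The brightest-probe alternative was not run because each gene has 1 probe. Signal over background limits the rest: mutant 7 read 9.62% of probes above background.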

Other observations

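The tests of the COX1 intron probes, of the Leu3 targets, of whole chromosomes and of a deleted stretch were chosen only after the result was seen, as were the annotation terms and the splits within slide rows or with averaged pairs.

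Further genes of ribosome assembly and of transcription by the polymerases that make ribosomal and transfer RNA fell in the mutant. In a test of 77 process terms given with the probes, 13 passed (camera), 2 higher and 11 lower. Of 13 genes of large ribosomal subunit assembly 9 fell and 0 rose, among them MAK21 at -1.01 and, above background on no mutant array, NIP7 at least 1.34-fold and RPF2 at least 1.24-fold lower (median -0.76, adjusted p = 0.000131, but adjusted p = 0.206 with an estimated correlation). Of 25 genes of primary rRNA transcript processing 12 fell and 0 rose, among them the helicases MTR4 at -0.97 and, above background on no mutant array, HCA4 at least 1.12-fold lower (adjusted p = 0.000349, but adjusted p = 0.206 with an estimated correlation). The term for transcription from polymerase III promoters had 4 of 10 genes lower and 0 higher (camera adjusted p = 0.0191, but adjusted p = 0.296 with an estimated correlation). RPC37 stood at -0.95 and RPC34 at -0.87. The term for transcription from polymerase I promoters had 5 of 18 genes lower and 0 higher (camera adjusted p = 0.0383, but adjusted p = 0.434 with an estimated correlation). RPC19, a subunit that polymerases I and III share, was above background on no mutant array and was at least 1.35-fold lower. Of these 13, 25, 10 and 18 genes, 2, 1, 0 and 6 are also in the lists of the report.

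Genes of translational elongation went both ways. Of 12 genes 6 fell, 1 rose and 5 did not pass (median -0.49, adjusted p = 0.0405, but adjusted p = 0.249 with an estimated correlation and 0.0697 within gain 600). The cytosolic factors TEF1 at -1.05, TEF2 at -0.84 and EFB1 at -0.79 fell. TEF1 and TEF2 are near-identical copies whose probes can bind both transcripts. Of the mitochondrial factors, MEF1 rose by 1.17 and MEF2 fell by 0.87. In the term protein complex assembly 6 of 11 genes rose and 0 fell, among them SCO1, CBP3 at 0.93 and FMC1 at 0.67, which act in assembly of respiratory complexes and ATP synthase (adjusted p = 0.0118, but adjusted p = 0.351 with an estimated correlation). With an estimated correlation 0 of the 77 terms passed in camera, where 13 passed with the preset one. All genes named here lie outside the rule for named genes, SCO1 excepted, and were chosen after their values were seen.

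Chance splits of the arrays were counted for each total. Of the 35 ways to part 8 arrays into 4 and 4, only the real one gave 1667 genes, and the highest other gave 0. Chance can be excluded for this count (1 of 35, the lowest share possible) only if the 8 arrays are separate and exchangeable. That is not settled, since several pairs were very close, and the measure from duplicate spots cannot tell shared RNA from separate cultures. Each slide row also holds 1 array of each strain. For genes at least 2-fold different the real count was 243 and the highest other 0 (1 of 35), and the same condition applies. Swaps within slide rows make only 8 splits, and 3 against 3 samples with the 2 close pairs averaged only 10. Both are too few for a share under 0.05, so these splits cannot exclude chance. There the real counts were 1667 and 1145 genes, with 243 and 286 at least 2-fold different, and the highest others 0. For gene lists the real count was 15 and 2 of 35 splits reached it, so chance cannot be excluded by this count. The other such split, also with 15 lists, keeps 3 of the 4 mutant arrays together, and among the 18 splits with 2 mutant arrays on each side the highest count was 1.

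The probes AI2, AI5_ALPHA and AI5_BETA were low in the mutant while COX1 itself was higher. Dim mutant arrays are argued against by lower bounds over the 5 arrays of gain 600. There AI2 was at least 3.84-fold, AI5_ALPHA 10.3-fold and AI5_BETA 1.39-fold lower, with a median bound of 1.94 in log2. The mutant arrays among these 5 were only the close pair of mutants 1 and 3. For AI5_ALPHA the call ended with 75th percentile scaling. Less mitochondrial RNA in general is argued against as well. On the 5 arrays of gain 600, the other 8 mitochondrial probes above background on at least 3 parent arrays had a median of 0.164 (SD 0.52). These include COX1 itself, the highest at 1.21. Without the intron probe AI1 the median was 0.12 (SD 0.50). As a hypothesis that was not tested, these introns may be missing from or changed in the mutant's mitochondrial DNA. Where the COX1 probe and the intron probes lie in the gene, and which introns KA31a carries, could not be checked. Changed splicing or decay would give the same values and stays open, as does slide column, which cannot be told apart from strain.

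The cytosolic ribosomal protein genes fell as a list, with a median of -0.87. On the quantile-normalized values, 10000 random lists matched on mean signal had medians that centred on 0.050, and 0 reached -0.87. The list thus fell below equally bright genes. Quantile normalization evens out shifts shared by probes of like brightness, so this centre was largely fixed beforehand. It cannot decide whether bright probes read low in general on the unnormalized arrays. Dim arrays are argued against by a median of -1.01 over the 5 arrays of gain 600, of which only the close pair of mutants 1 and 3 are mutant. The scaling is argued against by medians of -0.87 or lower with 75th percentile and median scaling. A difference in growth state at 48 h may lie behind the fall, as a hypothesis that was not tested, and slide column stays open.

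The branched-chain genes that fell include textbook targets of the regulator Leu3. Of 9 such targets all 9 fell (LEU1, LEU2, LEU4, ILV2, ILV5, BAT1, MAE1, OAC1 and GDH1), with a median of -1.79, and of -1.92 within gain 600. Among 10000 random lists of 9 amino acid synthesis genes, 0% had a median as low, while the 53 amino acid genes outside the list had a median of -0.33 with 23 lower. A lower activity of Leu3 in the mutant may account for this, as a hypothesis found and tested on the same data. Slide column stays open here too, and LEU2 is also a laboratory marker.

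Each chromosome's median of log2 differences was taken relative to that of all genes compared. It ran from -0.09 on chromosome I to 0.13 on chromosome VI, the farthest of 16, which argues against a gained or lost chromosome. A deleted stretch stays open. Over 5737 genes in order, the longest run of neighbours called at least 2-fold lower was 2 genes, and the 95th percentile of random orders was 3. That count can miss a deletion, because genes near background cannot show such a fall and break a run. Among 4139 genes above background on parents 2, 4 and 6, the longest run of neighbours at background on mutants 1 and 3 was 5 genes, RPC19, DBP2, CYB5, NOP15 and YAF9. Of 1000 random gene orders 0 held a run as long, and their 95th percentile was 3. All 5 were above background on 3 parent arrays and no mutant array, but DBP2 (adjusted p = 0.105) and YAF9 (a log2 difference of 0.00, adjusted p = 0.993) did not pass, so a loss cannot be told apart from low expression of neighbours near background. RPC19 and NOP15 are essential genes by textbook knowledge, which would speak against their loss in a living strain if it is haploid. The ploidy was not checked here.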
